A study of Mus musculus with 12 samples.

How the data were processed

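Gene expression was measured in granule cell progenitors, the dividing cells of the outer layer of the developing cerebellum, taken from mice at postnatal day 8. Wild type progenitors were compared with progenitors carrying SmoM2, an activated form of Smoothened, a signal transducer of the hedgehog pathway, fused to YFP. The SmoM2 allele lies at the Rosa26 locus behind a stop cassette, and a tamoxifen-dependent Cre recombinase under Atoh1 control switched it on after 200 µg of tamoxifen per g was given at postnatal day 2. Per the labels, the mice were of mixed C57BL/6 and Swiss Webster background, and cells of the hemispheres and of the vermis were isolated on a Percoll gradient with 5 mice pooled for each replicate. The 4 groups (wild type hemisphere, wild type vermis, SmoM2 hemisphere and SmoM2 vermis) had 3 arrays each, 12 in all, and each sample was placed in its group by its title. Whether the wild type mice received tamoxifen is not given in the sources used here.

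Total RNA was converted to biotin-labelled cRNA and hybridised to Affymetrix 3' expression arrays for the mouse genome, per the labels' protocols. The deposited values are log2 expression values per probe set, and per the submitters' processing notes the authors made them with Partek and RMA, which subtracts background, quantile-normalizes and summarises the probes of a set. The versions of both tools and any further filter are not given in the sources used here. RMA leaves no detection call, so a probe set near the lowest values of an array has no known distance from background, and differences there are compressed. The deposited log2 table held 45101 probe sets, including 64 hybridisation and labelling controls, and all 12 value columns were used.

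Probe sets were named through the platform annotation, in which 34958 had 1 gene symbol, 932 had several and 9211 had none. Of the probe sets with 1 symbol, 34754 had a gene identifier found in the reference gene table, and 0 symbols changed on updating. For each of 18194 genes the probe set with the highest mean over the 12 arrays was kept. For 9182 genes there was only 1 probe set, and 9012 had several. The deposited values were not normalized again for the reported results.

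Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 linear model with a mean for each of the 4 groups and 8 residual degrees of freedom per gene before moderation. The 5 contrasts were hemisphere minus vermis in wild type, SmoM2 minus wild type in the hemisphere, the same in the vermis, hemisphere minus vermis in SmoM2, and the difference between both SmoM2 effects (interaction). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 18194 genes of a contrast, and all tests were two-sided. The number of arrays, 3 per group, limits the precision, and the median SD between the 3 arrays of a group was 0.16 on the log2 scale.

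Fixed gene lists, 31 in all (20 of pathways and processes, 11 of cell types and sex-linked transcripts), were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the 31 lists of a contrast. Of 647 different genes on the lists 606 were measured. Members that passed were also counted with p adjusted over the list alone. With a correlation estimated for each list, none of the list calls held: 0 lists passed in any of the 5 contrasts, where the smallest adjusted p were 0.063, 0.068, 0.057, 0.3 and 0.55 in the order of the contrasts given above. At an unadjusted p under 0.05 the numbers of lists with that setting were 4, 11, 9, 3 and 1. The set test fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, passed 3, 17, 19, 1 and 0 lists.

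Named genes followed a rule. It took the 10 largest differences each way among genes that passed and whose 3 arrays of one group all lay on one side of the 3 of the other (for the interaction, an adjusted p under 0.05 alone). Where none passed, it took the 5 genes with the smallest p. Up to 4 members of each list and a set of hedgehog, granule cell and regional genes were added, and not all are named in the text. Groups, contrasts, lists, this rule and most alternatives were fixed before the data were examined.

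The model was tested on simulated data with 200 of the 18194 genes changed. At a change of 1.5-fold it recovered 47.8% of changed genes for the wild type region contrast, 50.7% and 55.2% for the SmoM2 contrasts in the hemisphere and the vermis, 52.2% for the SmoM2 region contrast and 13.4% for the interaction. At 2-fold these shares were 92.5%, 94%, 91%, 91% and 64.2%, and at 4-fold 100% for the 4 contrasts between groups and 98.5% for the interaction. Calls among unchanged genes numbered 19, 8, 6, 8 and 0 in the same order. In a simulation of the 31 lists for the SmoM2 contrast in the hemisphere, the 1 changed list was called and 0 others were. All simulated genes varied independently of each other and without differences between pools. The simulations therefore do not show how often lists of correlated genes are called without a change.

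The replicate numbers of the labels were checked for pairing through the correlation of deviations from the group means. Same-numbered hemisphere and vermis arrays of 1 genotype correlated at 0.142 to 0.527 in all 6 pairs, above the minimum of 0.1 set for pairing. Different numbers correlated at -0.404 to 0.0212. All 12 arrays correlated best with their own number in the other region. The labels do not say that both regions of a number came from the same mice, so the pairing rests on these correlations. Same-numbered arrays of both genotypes in 1 region correlated at -0.224 to 0.177 and were not taken as pairs. Fits with the replicate number as a block were run as alternatives. A fixed block within each genotype and a random block for the pool (estimated correlation 0.359) were added after this check.

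Other alternatives were all probe sets tested, the mean of the probe sets of a gene, only the 11132 genes above the median of all probe sets, trended and robust moderation, no moderation, only the groups compared, renewed quantile normalization, median centring, array quality weights, stricter thresholds and leaving out each array in turn. Probe sets with several symbols or none were tested separately and not named. Cells or RNA from the 5 mice of a pool cannot be told apart, so the spread measured is that between pools.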

Results

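The series asks how a strong hedgehog signal acts on granule cell progenitors of the lateral cerebellum (hemispheres) and of the midline (vermis), since these cells can give rise to medulloblastoma. Expression was measured on 12 arrays, 3 for each combination of genotype and region, each array from a pool of 5 mice at postnatal day 8. Array medians lay between 4.81 and 4.87 on the log2 scale, lower quartiles between 3.24 and 3.42 and upper quartiles between 6.90 and 7.10. Arrays of 1 group correlated at 0.989 to 0.997 and arrays of different genotypes at 0.981 to 0.989. The first principal component held 56.2% of the variance and separated the genotypes, with wild type arrays from -31.23 to -14.1 and SmoM2 arrays from 22.93 to 26.86. The next components held 10.6% and 7.46%.

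Some technical measures differed between groups. The 3'-to-5' difference of Actb probe sets, a measure of RNA integrity and labelling, was 0.64 ± 0.17 (SD, n = 3) in wild type hemisphere, 0.89 in wild type vermis, and 0.98 and 0.96 in SmoM2 hemisphere and vermis. The dap control transcript read 8.98 ± 0.86 (SD, n = 3) in wild type hemisphere and 10.4, 10.7 and 10.7 in wild type vermis, SmoM2 hemisphere and SmoM2 vermis. It was lowest, at 8.06, in wild type hemisphere replicate 3, where the bioB control read 7.15. Probe sets for 18S rRNA averaged 10.55 and 10.65 in wild type hemisphere and vermis and 11.18 and 11.23 in SmoM2. Xist, expressed from the inactive X chromosome, was present in every group at 11.3, 11.1, 11.7 and 11.7, and Y-linked genes averaged 6.15, 6.22, 5.51 and 5.57 in the same order. Of 4 sex-linked transcripts tested, the Y-linked Eif2s3y was lower in SmoM2 (-0.93 in the hemisphere, adjusted p = 0.0432, and -0.94 in the vermis, 0.0381), the others did not pass and neither did the list (0.515 and 0.602). Its adjusted p in the hemisphere was 0.167 without wild type hemisphere replicate 3, 0.05 without wild type vermis replicate 1, 0.118 and 0.159 without SmoM2 hemisphere replicates 1 and 2, and 0.0564, 0.0507 and 0.0535 without SmoM2 vermis replicates 1, 2 and 3. In the vermis it was 0.156 without wild type vermis replicate 3, 0.0507 without SmoM2 hemisphere replicate 1, and 0.074, 0.14 and 0.0598 without SmoM2 vermis replicates 1, 2 and 3. The call also ended without moderation (0.14 and 0.13) and in the hemisphere with array quality weights (0.158) or only the groups compared (0.0637). The sex of the pooled mice is not given in the sources used here.

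In hemisphere progenitors, feedback genes of the hedgehog pathway were higher in SmoM2. Gli1, a transcription factor and readout of the pathway, rose 3.21-fold (log2 difference 1.68 ± 0.15 SE, n = 3 arrays per group). Ptch1, the receptor for the ligand, rose by 1.69 ± 0.10, and Hhip, a membrane protein that binds hedgehog ligand, rose 6.3-fold (2.66 ± 0.23). Ccnd1, a cyclin of the G1 phase, rose by 1.37, and Atoh1, the transcription factor that keeps progenitors dividing, by 0.82 (adjusted p = 0.000363). Neurod1, a factor of granule cell differentiation, fell by 0.85 and Cntn2, an adhesion molecule of early granule neurons, by 0.90. Sowaha rose from 2.48 to 9.28. Other genes that rose included Nptx1 (a neuronal pentraxin), Vip (a neuropeptide), Crym (a thyroid hormone binding protein), Cbln4, Sema3e (a semaphorin) and Pdlim3, by 3.25 to 4.77. The wild type levels of Sowaha and Cbln4 (2.93) lay below the lower quartile of every array, and those of Vip (3.38), Nptx1 and Sema3e (3.57) within or just above these quartiles. Differences are compressed there, so the sizes of these rises give no order. Genes that fell included Slc17a6, a vesicular glutamate transporter (12.6-fold, -3.65), Igfbp5, a binding protein for insulin-like growth factors (-2.84), Dmrta1 (-2.46) and Ogn (-2.21).

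By limma, 2694 of 18194 genes passed in the hemisphere (14.8%), 1387 higher and 1307 lower in SmoM2, and 405 of them differed at least 2-fold (268 higher, 137 lower). All 3 arrays of one genotype lay above all 3 of the other for 31.7% of genes, where chance gives 10%. Normalizing again by quantiles gave 1076 higher and 1538 lower. The count was 4276 without wild type hemisphere replicate 1, 1633 without SmoM2 hemisphere replicate 1, 1705 without SmoM2 hemisphere replicate 3 and 2092 without wild type hemisphere replicate 3, the array with the low control transcripts.

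In vermis progenitors the same hedgehog genes were higher in SmoM2. Gli1 rose 2.83-fold (adjusted p = 7.84e-06), Ptch1 by a log2 difference of 1.83 ± 0.10 (SE, n = 3 arrays per group), Hhip 6.09-fold (2.61 ± 0.23) and Ccnd1 by 1.60 (adjusted p = 4.99e-06). Atoh1 rose by 0.85, while Neurod1 fell by 0.82 and Cntn2 by 1.07. Sowaha rose by 6.12, and others that rose included Nptx1 (4.83), Foxa2, a forkhead factor of the floor plate and endoderm (3.80), Vip (3.53), Cbln4 (3.53), Saa1, an acute phase protein (3.50), and Rbp4, a retinol carrier (3.38). In wild type vermis Saa1 (2.54) and Cbln4 (2.80) lay below the lower quartile of every array, Vip (3.36) within these quartiles and Sowaha (3.50) just above them, so these sizes give no order either. Genes that fell included Slc17a6 (-3.24), Igfbp5 (-2.70), Dmrta1 (-2.20) and Eomes, a transcription factor of unipolar brush cells (-2.15). Mobp and Ugt8a, which serve myelin formation, fell by 1.93 and 1.91.

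In the vermis 3096 genes passed by limma (17%), 1375 higher and 1721 lower in SmoM2, of which 444 differed at least 2-fold (256 higher, 188 lower). Median centring gave 1503 higher and 1334 lower, and only brighter genes tested gave 1417 and 1217, so the balance of rises and falls has no settled direction. Groups were fully separated for 39.8% of genes, against 10% by chance. The count was 1873 without wild type vermis replicate 2, 1920 without wild type vermis replicate 3, 1795 without SmoM2 vermis replicate 1 and 1756 without SmoM2 vermis replicate 2.

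**Figure D1:**
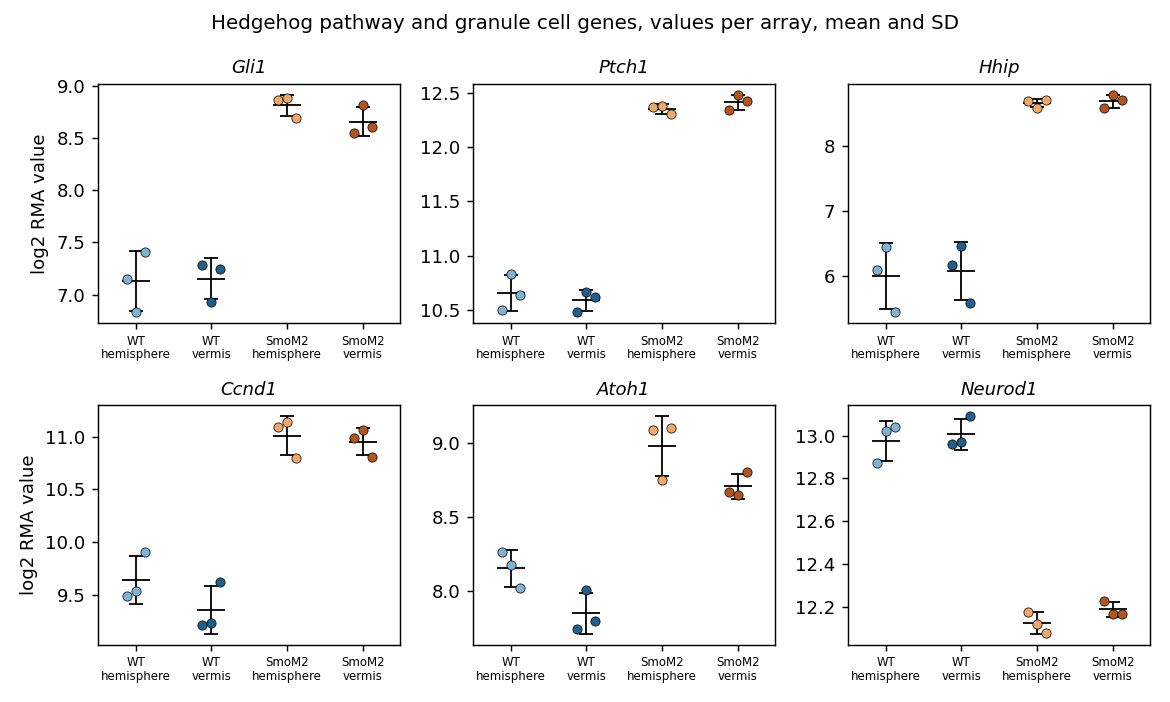
Log2 RMA values of Gli1, Ptch1, Hhip, Ccnd1, Atoh1 and Neurod1 on each of the 12 arrays (points), by group on the x axis, with the group mean (bar) and SD (error bar, n = 3). The first 5 genes lie higher in SmoM2 than in wild type in both regions, and Neurod1 lies lower, by 0.85 in the hemisphere and 0.82 in the vermis.

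Among hedgehog target genes, 6 of 11 rose and 1 fell in the hemisphere, with the same counts in the vermis. The 1 that fell in each was Igf2, an insulin-like growth factor (-0.60 and -0.73, named after its values were seen). Adjusted over the list alone, 7 rose and 2 fell in the hemisphere and 7 rose and 1 fell in the vermis. The fixed list as a whole was higher in SmoM2 (adjusted p = 2.08e-05 and 7.68e-06 in hemisphere and vermis; adjusted p = 0.068 and 0.057 with an estimated correlation). Genes of hedgehog transduction and the primary cilium included 9 of 22 that rose in the hemisphere and 8 in the vermis, with 0 lower, and adjusted over the list alone 12 and 11 rose (adjusted p = 1.48e-05 and 0.000645; adjusted p = 0.068 and 0.15 with an estimated correlation). The ligand co-receptors Gas1 (1.10 and 0.96), Cdon (0.82 and 0.76) and Boc (0.68 and 0.64) rose in both regions. The kept Smo probe set, 1 of 3 of the gene, rose by 0.46 in the hemisphere (adjusted p = 0.00852). It differed by 0.28 in the vermis (adjusted p = 0.0741). Whether it reads the transgenic transcript is not given in the sources used here, and the other Smo probe sets are not given here. Mycn, a target of the pathway in progenitors, differed by 0.41 in both regions and did not pass (adjusted p = 0.0556 and 0.055). It passed with the replicate number as a fixed block (0.0389 and 0.0383) and with the pool as a random block (0.0412 and 0.041). Its adjusted p in hemisphere and vermis was 0.0106 and 0.0236 without wild type hemisphere replicate 3, without wild type vermis replicate 3 0.0374 and 0.023, and in the vermis 0.0435 without wild type hemisphere replicate 1. Trended and robust moderation gave 0.0276 and 0.029 for Mycn and 0.0433 for Smo in the vermis. Mycn passed in both regions also with array quality weights (0.031 and 0.0183), median centring (0.0476 and 0.0406) and only brighter genes tested (0.0431 and 0.046), and Smo in the vermis with the weights (0.039).

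Genes of DNA replication and the G1/S transition rose in 11 of 28 cases in the hemisphere and 16 in the vermis, with 0 lower. Cdc6, which loads the replicative helicase, rose by 0.59 and 0.62, with Mcm4 rising by 0.58 in the hemisphere and Mcm3 by 0.63 in the vermis, both parts of that helicase. Adjusted over the list alone, 13 and 19 rose (list adjusted p = 3.73e-07 and 6.94e-11; adjusted p = 0.098 and 0.071 with an estimated correlation). Genes of mitosis rose in 1 of 29 cases in the hemisphere and 9 in the vermis, and in 0 and 14 adjusted over the list alone (list adjusted p = 0.00124 and 9.6e-09; adjusted p = 0.6 and 0.32 with an estimated correlation). Kif2c, a mitotic kinesin, was higher by 0.61 in the vermis (adjusted p = 0.0132, and 0.062 without wild type vermis replicate 3). It was the 1 mitosis gene to pass in the hemisphere (0.48, adjusted p = 0.0449), where its adjusted p was 0.161 and 0.136 without wild type hemisphere replicates 2 and 3. It was 0.0562 without wild type vermis replicate 2, 0.103, 0.14 and 0.0643 without SmoM2 hemisphere replicates 1, 2 and 3, and 0.0608, 0.061 and 0.0584 without SmoM2 vermis replicates 1, 2 and 3. Mki67, a proliferation marker, differed by 0.24 and 0.28 and did not pass (adjusted p = 0.11 and 0.0661, the latter 0.0373 without wild type vermis replicate 1). Ccnd2, a second D-type cyclin, was at -0.24 (adjusted p = 0.104) in the hemisphere and -0.18 (0.202) in the vermis. With trended and robust moderation the adjusted p was 0.0264 and 0.0116 for Mki67 in hemisphere and vermis and 0.0146 for Ccnd2 in the hemisphere. Without moderation it was 0.0433 for Ccnd2 in the hemisphere and 0.0416 for Mki67 in the vermis, where Mki67 also had 0.0461 with only brighter genes tested and 0.0335 with array quality weights. Ribosome biogenesis genes rose in 12 of 24 cases in the hemisphere and 18 in the vermis, with Polr1a, the large subunit of RNA polymerase I, up by 0.90 and 0.87. Over the list alone 20 rose and 1 fell in the hemisphere and 22 rose in the vermis (list adjusted p = 2.32e-09 and 3.71e-11; adjusted p = 0.068 and 0.057 with an estimated correlation). In the hemisphere the mitosis call ended without wild type hemisphere replicate 3 (0.074) and with only brighter genes tested (0.061).

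Of 27 genes of granule neuron differentiation, 12 fell and 1 rose in the hemisphere and 14 fell and 0 rose in the vermis. Those that fell included the netrin receptor Unc5c (-1.70 and -1.83), the adhesion molecule Cntn1 (-1.39 and -1.74) and the microtubule regulator Stmn2 (-1.37 and -1.18). Adjusted over the list alone, 13 fell and 2 rose in the hemisphere and 14 fell and 1 rose in the vermis (list adjusted p = 1.48e-05 and 3.13e-07; adjusted p = 0.068 and 0.057 with an estimated correlation). Synapse and axon genes passed as a list in the vermis, where 12 of 27 fell and 4 rose, or 14 and 4 over the list alone (adjusted p = 0.0118, and 0.25 with an estimated correlation; 0.05 without wild type vermis replicate 1), and in the hemisphere 8 fell and 4 rose (10 and 5 over the list alone, list adjusted p = 0.0726). The light neurofilament Nefl fell by 1.39 and 1.73, and Cplx2, a regulator of vesicle release, rose by 1.90 and 1.12. Of 13 genes of progenitor identity, 1 rose in each region (Atoh1), and 3 fell in the hemisphere and 2 in the vermis, Pax6 by 0.55 and 0.56, and the list did not pass in either region.

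Signalling and adhesion genes changed in both directions. Notch pathway genes rose in 8 of 20 cases in each region, with 1 lower in the vermis, and over the list alone 9 rose in the hemisphere and 8 rose and 2 fell in the vermis (list adjusted p = 2.08e-05 and 0.00655; adjusted p = 0.068 and 0.21 with an estimated correlation). The ligand Jag1 rose by 2.33 and 1.91 and the receptor Notch2 by 1.11 and 1.28. The IGF and growth factor list held 12 genes that rose and 3 that fell of 26 in the hemisphere and 13 and 2 in the vermis, with 13 and 3, and 13 and 2, over the list alone (list adjusted p = 1.48e-05 and 1.06e-05; adjusted p = 0.069 and 0.1 with an estimated correlation). Its members included Etv5, an ETS factor downstream of receptor tyrosine kinases (2.88 and 2.97), the ligand Pdgfa (2.55 and 2.34) and Spry4, an inhibitor of such kinases (1.67 and 1.97). Cadherins and protocadherins rose in 11 and fell in 2 of 24 cases in the hemisphere (12 and 3 over the list alone) and rose in 10 and fell in 2 in the vermis (12 and 4), with Cdh20 up by 2.26 and 2.17 (list adjusted p = 0.000548 and 0.000313; adjusted p = 0.094 and 0.1 with an estimated correlation). Wnt pathway genes rose in 10 and fell in 4 of 29 cases in the hemisphere, 12 and 7 over the list alone (adjusted p = 0.0247, and 0.13 with an estimated correlation), and rose in 8 and fell in 5 in the vermis (adjusted p = 0.139, where the median was -0.05 and the mean 0.17). The receptor Fzd1 rose by 1.53 and 1.58 and the stem cell marker Lgr5 by 1.32 and 1.77. Immediate early and dissociation stress genes rose in 5 and fell in 1 of 26 cases in the hemisphere, 6 and 2 over the list alone (adjusted p = 0.0247, and 0.29 with an estimated correlation), with Egr3 at 1.43, and 4 rose and 1 fell in the vermis (adjusted p = 0.139). The Wnt and immediate early lists had adjusted p of 0.11 and 0.082 in the hemisphere without wild type hemisphere replicate 1. The immediate early list had 0.05 without SmoM2 hemisphere replicate 3 and 0.077 after renewed quantile normalization. With only brighter genes tested, the Wnt and immediate early calls of the hemisphere and the Notch call of the vermis ended (0.19, 0.22 and 0.079).

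Cholesterol synthesis genes fell in 7 of 19 cases in the hemisphere and 5 in the vermis, or 8 and 5 over the list alone, with the sterol reductase gene Tm7sf2 at -0.70 and -0.75 (list adjusted p = 0.0226 and 0.0445; adjusted p = 0.5 and 0.52 with an estimated correlation). The hemisphere call ended without wild type hemisphere replicate 1 (0.19), and the vermis call without wild type vermis replicates 1 (0.17) or 2 (0.11), without SmoM2 vermis replicates 2 (0.056) or 3 (0.13), and with the mean of all probe sets of a gene (0.059).

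Markers of other cell types that a Percoll fraction can hold were also measured. Among 17 oligodendrocyte lineage genes 12 fell in each region and 3 rose. Those that fell included the myelin genes Mog (-1.54 and -1.83) and Ugt8a (-1.47 and -1.91), whereas Olig2 and Olig1, transcription factors of the lineage, rose by 2.10 and 1.75 in the hemisphere. Over the list alone 13 fell and 3 rose in the hemisphere and 12 fell and 3 rose in the vermis (list adjusted p = 8.83e-05 and 1.34e-06; adjusted p = 0.44 and 0.28 with an estimated correlation). Microglia and macrophage genes fell in 12 of 19 cases in each region, or 17 and 16 over the list alone, with the protease Ctss at -1.31 and -1.08 and the receptor Csf1r at -1.09 in both (list adjusted p = 2.32e-09 and 1.34e-06; adjusted p = 0.068 and 0.13 with an estimated correlation). GABAergic interneuron genes fell in 7 of 10 cases in the hemisphere and 9 in the vermis, or 8 and 9 over the list alone, with Tfap2b (-1.24 and -1.47) and Ptf1a, which specifies inhibitory neurons (-1.02 and -1.13), among them (list adjusted p = 2.87e-05 and 3.13e-07; adjusted p = 0.068 and 0.057 with an estimated correlation). Endothelium and pericyte genes fell in 6 of 19 cases in the vermis, or 11 over the list alone, with the transporter Slco1a4 at -1.56 (adjusted p = 0.000645, and 0.43 with an estimated correlation). In the hemisphere 2 of them fell and the list did not pass. Astrocyte and Bergmann glia genes did not pass as a list in either region, with 6 higher and 4 lower of 20 in the hemisphere and 7 and 4 in the vermis. Nes (1.18 and 1.10) and Sox9 (1.05 and 0.93), which neural stem cells also express, rose, while the median of that list was -0.24 and -0.07 against a test direction of higher. In the choroid plexus and ependyma list, Clic6 rose by 2.39 and 1.66 and the list did not pass.

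**Figure D2:**
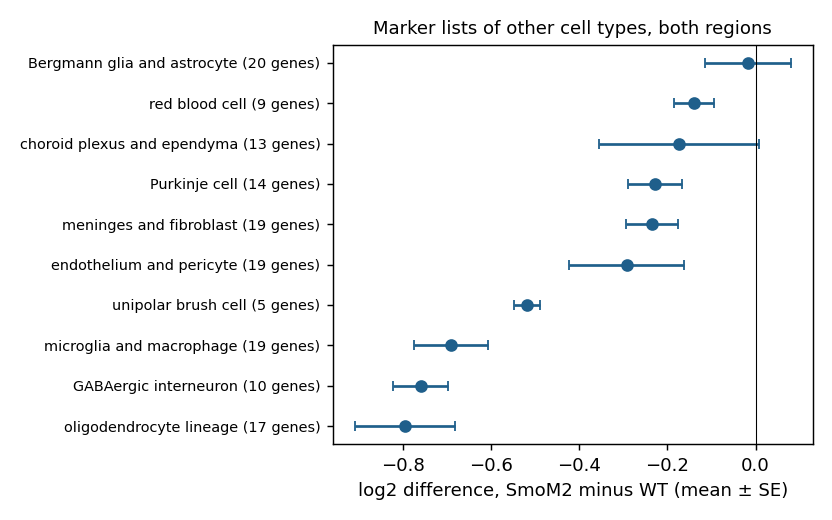
Mean log2 difference between SmoM2 and wild type over both regions for the measured genes of each marker list (points) with the SE (bars), 12 arrays. The SE treats the 12 arrays as independent and takes no account of the pairing of the numbers, so it can be too small. Oligodendrocyte lineage (-0.795), GABAergic interneuron (-0.759) and microglia lists (-0.691) lie furthest below 0, and the astrocyte list lies at -0.0179.

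Whether SmoM2 acted differently in hemisphere and vermis was tested by the interaction. By limma 0 genes passed and every adjusted p was 1, and 564 of 18194 genes had an unadjusted p under 0.05. The count was also 0 without moderation, with the replicate number as a block and with the pool as a random block. The 5 genes with the smallest unadjusted p, none of which passed, were Rflna (-0.89), Matn4 (0.81), Adipoq (0.87), Dbx1 (-1.17) and the Notch regulator Lfng (-0.75), where a positive value is a more positive SmoM2 effect in the hemisphere. Without SmoM2 hemisphere replicate 3, Dbx1, a homeobox factor of spinal and hindbrain interneurons, passed at -1.41 (adjusted p = 0.0372). Across genes, the SmoM2 effects of both regions correlated at a Pearson r of 0.883 and a Spearman rho of 0.793, where genes are not independent replicates. Genes that passed in both regions numbered 1814 of the 3976 that passed in either, 958 higher and 856 lower in both, where independent lists would share 105 and 124, and 0 changed in opposite directions. With the pairing of the numbers, differences between pools can enter both effects and raise the correlation and the overlap. The counts for independent lists take no account of this.

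**Figure D3:**
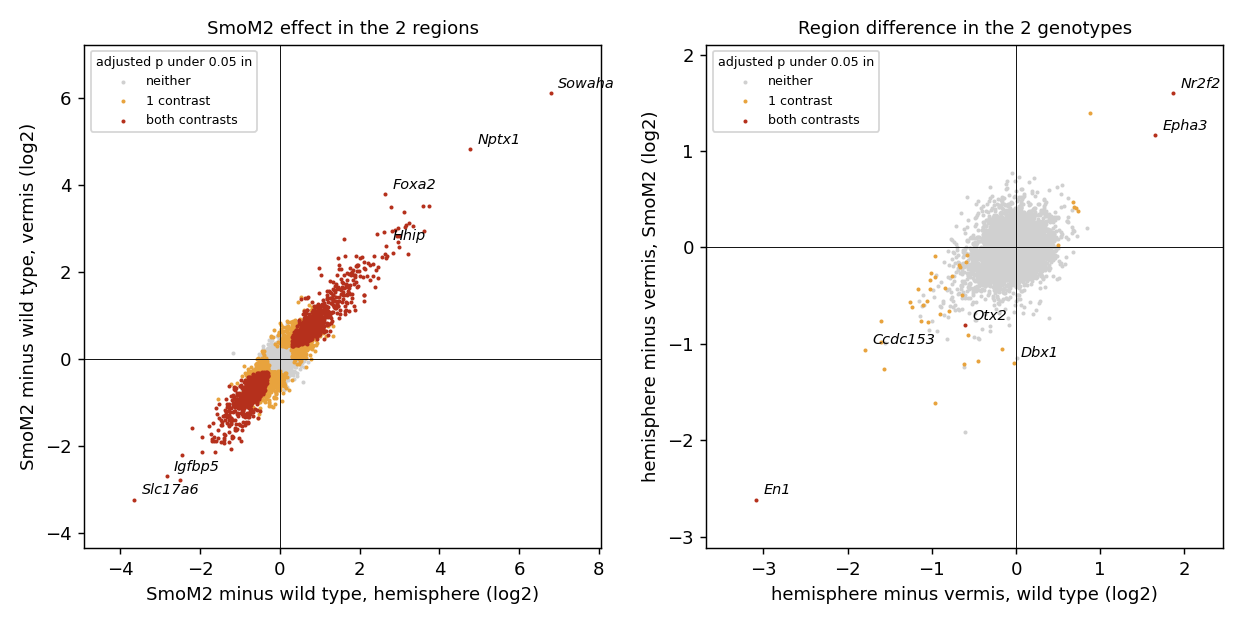
Log2 differences of 18194 genes (points), with the SmoM2 effect in the hemisphere (x) against the vermis (y) on the left and the hemisphere minus vermis difference in wild type (x) against SmoM2 (y) on the right, coloured by the contrasts passed at an adjusted p under 0.05. On the left 1814 genes passed in both contrasts and lie along the diagonal, and on the right 4 genes did.

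Although no gene passed, camera called 8 lists in the interaction. Oligodendrocyte lineage genes had a median of 0.41 (adjusted p = 2.7e-06), endothelium and pericyte genes 0.54 (1.09e-07), GABAergic interneuron genes 0.23 (0.00699), Purkinje cell genes 0.21 (0.023) and Notch genes 0.24 (0.0178). A positive median stands for a more positive SmoM2 effect in the hemisphere. Genes of mitosis had a median of -0.17 (8.87e-06), those of G1/S -0.08 (0.0142) and microglia genes -0.16 (0.00699). As hemisphere minus vermis, the medians in wild type and in SmoM2 were 0.16 and 0.02 for mitosis and 0.12 and 0.055 for G1/S. They were -0.46 and -0.003 for oligodendrocyte, -0.26 and -0.06 for Purkinje and -0.15 and 0.09 for interneuron genes. In all of these the wild type difference was the larger. It was the smaller for endothelium (-0.19 and 0.27), Notch (-0.09 and 0.12) and microglia genes (0.07 and -0.20). In none of these lists did a member pass over all genes, and adjusted over the list alone 1 Notch gene was higher and 1 lower. With a fixed block for each pool 9 oligodendrocyte, 4 endothelium and 2 Purkinje genes were also higher over the list alone, with the random block 4, 1 and 1 and 1 interneuron gene, and with the replicate number as a block 3 endothelium genes and 1 Purkinje gene. With an estimated correlation the adjusted p was 0.55 for the oligodendrocyte, endothelium, interneuron, Purkinje, Notch and microglia lists, 0.66 for mitosis and 0.61 for G1/S, so that 0 lists passed and 1 had an unadjusted p under 0.05, and fry called 0 lists, with 0 at an unadjusted p under 0.05. The Purkinje call ended with the mean of the probe sets of a gene (0.13) and the interneuron call with only brighter genes tested (0.13). Without wild type hemisphere replicate 1 only 2 lists passed, and without wild type vermis replicate 3 or SmoM2 hemisphere replicate 3, 5 each.

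In wild type progenitors few genes passed between hemisphere and vermis in the reported model, which takes no account of the pairing of the numbers. More passed with the pool as a random block, as given below. In the simulation 47.8% of 1.5-fold changes were recovered for this contrast, so genes that did not pass may still differ. The homeobox gene En1, which patterns the midbrain and cerebellum, was lower in the hemisphere (-3.08 ± 0.16 SE, n = 3 arrays per group). Its level of 2.53 there lay below the lower quartile of every array, against 5.61 in the vermis, so this compressed difference gives no exact fold. Nr2f2, an orphan nuclear receptor, was 3.65-fold higher in the hemisphere (1.87 ± 0.16), the ephrin receptor Epha3 3.15-fold higher (1.66 ± 0.16) and the related receptor gene Nr2f1 higher by 0.67. The transcription factors En2 (-0.64) and Otx2 (-0.61) were lower in the hemisphere. Several genes of motile cilia and ependyma were lower there too, among them Ccdc153 (-1.79 ± 0.30), Tmem212 (-1.61), Enkur (-1.60) and the radial spoke gene Rsph4a (-1.17), as were Ecrg4 (-1.57), the myelin gene Mal (-1.23), Pcp4, a calmodulin regulator of Purkinje cells (-1.01), Sowaha (-1.02, with the same limit as En1), Plp2 (-0.84) and Adipoq (-0.96), the last 3 named after their values were seen. Hedgehog genes showed no passing difference, with Gli1 at -0.02 (adjusted p = 0.999), Ptch1 at 0.07 (0.993), Ccnd1 at 0.29 (0.844) and Atoh1 at 0.30 (0.668).

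By limma 34 of 18194 genes passed between the regions of wild type (0.187%), 7 higher and 27 lower in the hemisphere, 17 of them at least 2-fold, and 1149 had an unadjusted p under 0.05. The groups were fully separated for 8.76% of genes, against 10% by chance if all 6 arrays were independent. The correlation within numbered pairs can lower that 10%, so these shares do not show that the regions differ no more than by chance. The adjusted p of 21 of the 34 lay between 0.03 and 0.05. With the pool as a random block 198 genes passed, 42 higher and 156 lower. With a fixed block for each pool, the adjusted p of named genes passed 0.05 for Ccdc153 (0.0569), Tmem212 (0.0722), Enkur (0.0719), Ecrg4 (0.0569) and Otx2 (0.0579). Tmem212 did not pass with the replicate number as a block either (0.0627), and Otx2 also had 0.0571 after median centring and Pcp4 0.0612 after renewed quantile normalization. Only En1, Epha3 and Nr2f2 passed when the 6 wild type arrays were fitted alone. The count was 58 without wild type hemisphere replicate 1, and without wild type hemisphere replicate 2 it was 9. Leaving out wild type vermis replicates 1, 2 or 3 gave 19, 8 or 9, SmoM2 hemisphere replicates 1, 2 or 3 gave 14, 14 or 10, and SmoM2 vermis replicates 1 or 2 gave 10 or 16. The calls of En1, Nr2f2, Epha3, Adipoq, Plp2 and Sowaha held without each of the 12 arrays. Without wild type hemisphere replicate 3, the array with the low control transcripts, 26 genes passed.

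**Figure D4:**
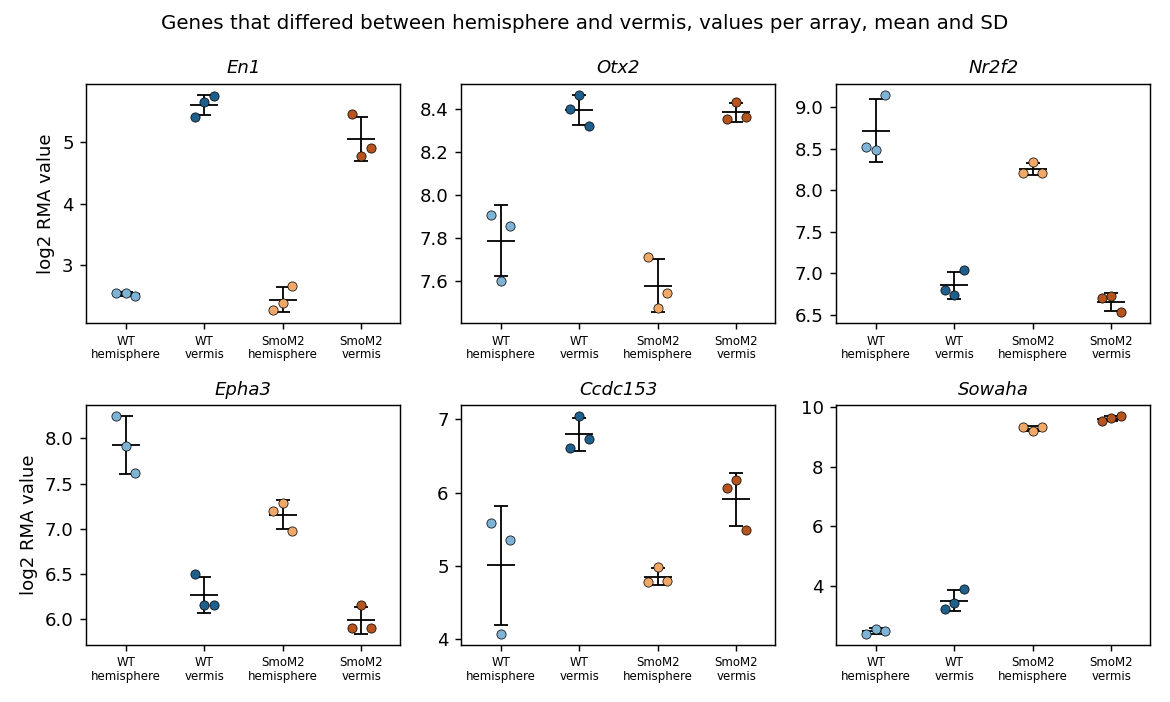
Log2 RMA values of En1, Otx2, Nr2f2, Epha3, Ccdc153 and Sowaha on each of the 12 arrays (points), by group on the x axis, with the group mean (bar) and SD (error bar, n = 3). En1 lies near 2.53 in wild type hemisphere and at 5.61 in wild type vermis, and Sowaha lies above 9 only in SmoM2.

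Among the fixed lists, regional patterning factors held 2 genes higher and 3 lower in the wild type hemisphere of 33 measured, and the list did not pass (adjusted p = 0.0638). Choroid plexus and ependyma genes were lower in the hemisphere in 4 of 13 cases, or 6 over the list alone (median -0.61, adjusted p = 6.93e-08, and 0.24 with an estimated correlation). The 4 were Ccdc153, Tmem212, Enkur and Otx2, which did not pass with a fixed block for each pool, as given above, where 6 still passed over the list alone. Their abundant transcript Ttr read 11.9 in wild type hemisphere replicate 1 and 4.90 and 5.17 in the other replicates of that group. It lay between 7.15 and 8.76 on the 6 vermis arrays and between 5.79 and 6.60 in SmoM2 hemisphere, and did not pass between the regions of either genotype (-0.61, adjusted p = 0.999, and -1.92, adjusted p = 1). Oligodendrocyte lineage genes, 0 of 17 over all genes and 9 over the list alone, were lower in the hemisphere (median -0.46, adjusted p = 9.32e-10, and 0.32 with an estimated correlation). Mobp (-0.89, adjusted p = 0.201) passed with the replicate number as a block (0.037), with a block for each pool (0.0385) and with the pool as a random block (0.0253). With the random block 4 of the 17 passed, the others being Mog (0.0409), Cnp (0.0292) and Olig1 (0.0235). So were Purkinje cell genes, 1 of 14 (Pcp4; median -0.26, adjusted p = 2.82e-06, and 0.063 with an estimated correlation) and immediate early genes, 0 of 26 (median -0.25, adjusted p = 2.08e-07, and 0.068 with an estimated correlation). Jund of the latter passed with a block for each pool (0.0352) and with the random block (0.0383), and Gabra2 of the interneuron list with the random block (0.0253). GABAergic interneuron genes, 0 of 10 and 1 over the list alone (adjusted p = 0.05 after rounding and just under the threshold before it, and 0.42 with an estimated correlation), and endothelium genes, 0 of 19 (adjusted p = 0.0376, and 0.65 with an estimated correlation), were lower too. Genes of mitosis were higher in the hemisphere, with all 29 differences positive, 0 passing and a median of 0.16 (adjusted p = 4.58e-08, and 0.48 with an estimated correlation), and so were G1/S genes, 0 of 28 (median 0.12, adjusted p = 2.23e-06, and 0.32 with an estimated correlation). The interneuron and endothelium calls both ended after renewed quantile normalization (0.065 each), and the interneuron call with the mean of the probe sets of a gene (0.1) and with only brighter genes tested (0.56). Without wild type hemisphere replicate 1 the adjusted p was 0.099 for mitosis, 0.21 for interneurons and 0.88 for endothelium. The endothelium call also ended without wild type hemisphere replicate 2 (0.3) and wild type vermis replicates 2 (0.12) and 3 (0.18). The interneuron call ended without wild type hemisphere replicate 3 (0.19), wild type vermis replicates 2 (0.23) and 3 (0.18) and SmoM2 hemisphere replicate 1 (0.059).

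In SmoM2 progenitors En1 (-2.62 ± 0.16 SE, n = 3 arrays per group, from a level of 2.44 in the hemisphere with the same limit) and Otx2 (-0.81) were again lower and Nr2f2 (1.60 ± 0.16) and Epha3 (1.17 ± 0.16) higher in the hemisphere. Other genes that passed were Insm2, a zinc finger gene (1.39), Fam107a (-1.61), Hsd11b1, which regenerates active glucocorticoid (-1.21), Dbx1 (-1.19), Cmtm7 (-1.17), Dsc2, a desmosomal cadherin (-1.05), and BC034090 (-0.91). By limma 11 genes passed, 3 higher and 8 lower in the hemisphere (0.0605%), 9 of them at least 2-fold, and 661 had an unadjusted p under 0.05. The groups were separated for 10.7% of genes, against 10% by chance if all 6 arrays were independent, a share that the pairing of the numbers can lower. With the pool as a random block 39 genes passed, 9 higher and 30 lower, and Dsc2 did not pass with a fixed block (adjusted p = 0.0545 with the replicate number and 0.0613 within the genotype). The count was 18 without wild type hemisphere replicate 1, 3 and 5 without SmoM2 hemisphere replicates 1 and 2, and 2, 5 and 3 without SmoM2 vermis replicates 1, 2 and 3. Fitted alone, the 6 SmoM2 arrays gave 15 genes, without Hsd11b1 (0.0576) and Dbx1 (0.0798). Only the calls of En1 and Nr2f2 held without each of the 12 arrays.

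Lower in the SmoM2 hemisphere as a list were choroid plexus and ependyma genes, 1 of 13 passing and, over the list alone, 7 lower and 1 higher (median -0.72, adjusted p = 6.3e-08, and 0.31 with an estimated correlation). The others lower were immediate early genes (median -0.14, adjusted p = 1.87e-05, and 0.3 with an estimated correlation), microglia genes (-0.20, adjusted p = 0.00631, and 0.6 with an estimated correlation) and cholesterol synthesis genes (-0.08, adjusted p = 0.0197, and 0.84 with an estimated correlation). Endothelium and pericyte genes were higher, 1 over the list alone (median 0.27, adjusted p = 2.67e-06, and 0.55 with an estimated correlation), as were Notch genes (0.12, adjusted p = 0.00738, and 0.41 with an estimated correlation). Over the list alone 4 endothelium genes were higher with each of the 3 blocks. In the last 5 of these lists no member passed over all genes. Eph and ephrin genes, 1 of 21 higher (Epha3; 2 over the list alone), had an adjusted p of 0.0743, and of 0.0328 and 0.0479 with the replicate number as a block over all arrays and within the genotype, the latter with 4 higher and 1 lower over the list alone. Without SmoM2 hemisphere replicate 3 the adjusted p was 0.28 for microglia, 0.097 for cholesterol synthesis and 0.18 for Notch, and without SmoM2 vermis replicate 1 it was 0.43, 0.41 and 0.17. Without SmoM2 hemisphere replicate 2, 10 lists passed.

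The region differences of both genotypes were compared. En1, Epha3, Nr2f2 and Otx2 passed in both, 2 higher and 2 lower, where independent lists would share 0.00115 and 0.0119. All 41 genes that passed in either genotype had the same sign in both, and of the 34 that passed in wild type 26 had an unadjusted p under 0.05 in SmoM2. Across all genes the correlation was 0.286 (Pearson) and 0.135 (Spearman), where genes are not independent replicates. The shared count of 4 was 10 without wild type hemisphere replicate 1 and 2 without each of SmoM2 hemisphere replicates 1 and 2 and SmoM2 vermis replicate 1.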

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

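The comparison of oligodendrocyte with meninges markers, its check on brighter members, the percentile among random lists and the splits within pairs were tests chosen only after the results they bear on were seen.

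In the interaction camera called 8 gene lists, although 0 genes passed by limma, with 564 at an unadjusted p under 0.05. With an estimated correlation 0 lists passed (smallest adjusted p 0.55, 1 list at an unadjusted p under 0.05), and fry called 0. The median difference of effects, hemisphere minus vermis, was 0.537 for endothelium and pericyte genes, 0.408 for oligodendrocyte lineage genes, 0.235 for Notch genes, 0.234 for GABAergic interneuron genes, 0.21 for Purkinje cell genes, -0.0751 for G1/S genes, -0.161 for microglia genes and -0.172 for mitosis genes. The adjusted p of the G1/S, mitosis, Notch, Purkinje, interneuron and microglia lists was 0.42, 0.16, 0.057, 0.057, 0.057 and 0.16 without wild type hemisphere replicate 1. Without SmoM2 hemisphere replicate 3 it was 0.11 for each of the G1/S, Notch and microglia lists, and without wild type vermis replicate 3 it was 0.096 for G1/S, 0.082 for mitosis and 0.096 for Purkinje genes. Without SmoM2 vermis replicate 1 the Notch and microglia lists had 0.14 and 0.17, and without wild type hemisphere replicate 2 the Notch list had 0.21. The Purkinje and interneuron lists had 0.21 and 0.063 without wild type hemisphere replicate 3. Without SmoM2 hemisphere replicate 2 they had 0.16 and 0.055. The Purkinje list had 0.055 without SmoM2 vermis replicate 3. Of 100 splits of the 12 arrays, 20 called as many lists as the real one, and the highest other split called 11, so chance is not excluded for the number of lists. These splits do not keep the pairing of the numbers. Of the 32 splits that exchange regions within numbered pairs of a genotype, 8 called as many lists, the highest other called 9, and chance is not excluded there either.

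For the interaction gene count of 0 the splits decide nothing, since all 100 must call at least as many. The highest other split called 85 genes. It kept the wild type labels and exchanged the regions of SmoM2, so it adds the region differences of both genotypes, a structure of the samples. It is also the highest of the other splits within pairs. For the 4 contrasts between groups, 10 splits are too few for a share under 0.05. The real split gave 34, 2694, 3096 and 11 genes (wild type regions, SmoM2 in hemisphere, SmoM2 in vermis, SmoM2 regions) and the highest other gave 0 in each, also among the 4 splits that part all numbers, so 1 of 10 was as large. For lists, 1 of 10 splits was as large for the wild type regions (8 lists, highest other 6), 2 of 10 for SmoM2 in the hemisphere (15, highest other 15), 1 of 10 for SmoM2 in the vermis (15, highest other 13) and 3 of 10 for the SmoM2 regions (6, highest other 7). Among splits parting all numbers the highest others were 5, 8, 10 and 3.

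Probe sets without a single gene symbol lay outside the gene comparisons, and 10092 of them were tested separately. By limma 1 of these 10092 passed between the wild type regions, 704 between genotypes in the hemisphere (401 higher, 303 lower in SmoM2) and 712 in the vermis (365 higher, 347 lower).

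Markers of oligodendrocytes, GABAergic interneurons and microglia were lower in SmoM2 over both regions, by mean shifts of -0.795 ± 0.113 (SE), -0.759 ± 0.0622 and -0.691 ± 0.0841. The prediction for a larger share of progenitors was that the lists of other cell types fall by about the same amount. The oligodendrocyte shift exceeded that of meninges genes (-0.235 ± 0.0582) by -0.56 ± 0.117, and by -0.665 ± 0.122 among brighter members, so both lists did not fall alike. Members of both lists moved both ways, and differences near background are compressed. Unequal list means therefore do not decide whether dilution contributed. Setting each array to the mean of its values above the upper quartile left the 3 lists at -0.827 ± 0.0611, against -0.748 ± 0.0614 as deposited. The upper quartiles of the arrays already lay between 6.90 and 7.10, so this step could move the lists little. It does not decide whether array scaling contributed. Dilution, array scaling and an effect of the genotype on these cells or on how many enter the gradient fraction stay open. Each may account for part of the fall.

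Motile cilium and ependyma genes were higher in the vermis. On a second list of 38 cilium genes, 32 of them measured, 0 in the earlier lists and 9 above the median of all probe sets, the vermis was higher in 6 of 6 pools by 0.334 ± 0.0729 (SE), exact sign-flip p = 0.0312, the smallest possible with 6 pools. The pattern was first seen in these same 6 pools, and the second list holds genes of the same kind. The p is therefore no independent support for it. An uneven split in wild type pools alone predicted a difference near 0 in SmoM2. Each of the 3 SmoM2 pools was higher in the vermis, by 0.281, 0.379 and 0.109. Their mean was 0.256 ± 0.079 (SE), against 0.411 ± 0.12 in wild type pools. This goes against that prediction, but 3 pools are too few to exclude the explanation. Ependymal cells carried over with the vermis meet the prediction and are a candidate explanation, though the Percoll gradient would be meant to remove them and the member with the brightest probe set, Tppp3, was at 7.27 and 7.60 in wild type hemisphere and vermis and 7.43 and 7.76 in SmoM2. Expression of these genes by the progenitors themselves, and a true regional difference, stay open and untested.

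Ttr, an abundant choroid plexus transcript, read 11.9 in wild type hemisphere replicate 1, against 4.90 and 5.17 in replicates 2 and 3 and 7.15 to 8.76 on the 6 vermis arrays. On a second list of 16 choroid plexus genes, 13 measured, 1 of them in an earlier list and 4 above the median of all probe sets, the median deviation of that array from the others of its group was 0.197, against at most 0.0971 in any of the other 11 arrays, and 9 of 13 members were higher. This lay at the 99.8th percentile of 10000 random lists matched on mean level. Their genes were drawn independently of each other, so a list of genes that vary together can reach too extreme a percentile. Choroid plexus tissue carried into that pool is a candidate explanation. Igfbp2, the member with the brightest probe set, read 8.79 against 8.56, Cab39l 7.30 against 6.43, while Sostdc1 was not higher at 3.78 against 3.84, and the Percoll gradient would be meant to remove such tissue. Outside the second list, Clic6 read 5.305 in that array, against 5.18 and 5.48 in replicates 2 and 3. Folr1 read 3.97 against 3.71 and 3.63, and Kcnj13 4.85 against 4.43 and 4.27. No biological explanation was tested.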

How the results depend on the processing

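Both pool blocks were alternatives chosen only after the pairing of the numbers was seen. All others were set before. No named gene or list call reversed its direction. The balance of calls did turn: in the hemisphere to 1076 higher and 1538 lower after renewed quantile normalization and 1348 and 1357 with the mean of the probe sets, and in the vermis to 1503 higher and 1334 lower after median centring and 1417 and 1217 among brighter genes. It also turned in the hemisphere without wild type hemisphere replicate 2 (891 and 910) and SmoM2 hemisphere replicate 2 (1015 and 1026), in the vermis with all probe sets (2562 and 2469), at 0.01 (674 and 660) and with 1.5-fold (729 and 691), and between wild type regions without moderation (3 and 2) and with only the groups compared (2 and 1). Of 290 calls of named genes over the 5 contrasts, 198 were the same in all alternatives, and of 52 list calls 25 were the same in all but the estimated correlation.

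In the wild type region contrast (34 genes), 19 passed among brighter genes only, 5 without moderation, 3 with only the groups compared, 15 with array quality weights, 5 at an adjusted p under 0.01 and 198 with the random pool block. For SmoM2 in the hemisphere (2694) the values were 4869 with all probe sets, which counts probe sets and not genes, 1753 with only the groups compared, 1262 at 0.01 and 1326 with at least 1.5-fold, and for the vermis (3096) 5031, 1334 at 0.01 and 1420 with 1.5-fold. For the SmoM2 regions (11) they were 1 without moderation, 42 with weights, 2 at 0.01 and 39 with the random pool block. Stricter thresholds lower counts by construction, and fitting fewer arrays leaves fewer residual degrees of freedom. For the other settings the cause was not tested. Lists that passed numbered 0 in each of the 5 contrasts with an estimated correlation (4, 11, 9, 3 and 1 at an unadjusted p under 0.05), and by fry 3 in the wild type regions, 1 in the SmoM2 regions and 0 in the interaction (0 at an unadjusted p under 0.05); fry does not compare a list with other genes.

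With the replicate block, that is with the arrays paired by number, 39, 3253, 3745, 12 and 0 genes and 8, 15, 15, 7 and 8 lists passed, and 2228 and 4 genes were shared between regions and between genotypes. With the replicate block within genotype the region contrasts and the interaction gave 49, 15 and 0 genes. Where a block moved by over 1.5 times a number of passing list members that the text gives for the regions or the interaction, the value stands beside it. Members of lists not counted there also passed under a block, among them Lfng (adjusted p = 0.0385 within genotype and 0.0066 with the random block), Sp5 (0.0385 within genotype) and Col1a1 (0.0456 and 0.0206 with the replicate and random blocks) in wild type, and Sfrp2 (0.0465 within genotype), En2 (0.0447) and Fgf8 (0.027, both with the random block) in SmoM2. Between genotypes, where same-numbered arrays were not taken as pairs, the replicate block gave 3 and 14 mitosis genes that rose in hemisphere and vermis, and in the vermis 10 endothelium genes, 4 cadherins, 8 patterning factors and 4 Eph genes that fell. With the random pool block the interferon gene Oas1a did not pass in the hemisphere (adjusted p = 0.054), where 2 patterning factors fell and 1 BMP gene rose. Over the list alone it gave 4 Wnt genes that fell in the hemisphere. Both blocks gave 1 immediate early gene that fell in the hemisphere over the list alone, and neither gave the granule neuron gene that rose in the vermis.

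Leaving out each array in turn gave 8 to 58 genes for the wild type regions, 1633 to 4276 for SmoM2 in the hemisphere, 1756 to 3827 in the vermis, 2 to 18 for the SmoM2 regions and 0 to 1 for the interaction. Lists ranged from 6 to 9, 12 to 16, 13 to 16, 4 to 10 and 2 to 12, and shared genes from 1281 to 2469 between regions and from 2 to 10 between genotypes. The lowest and highest values stood without wild type vermis replicate 2 and wild type hemisphere replicate 1 (wild type regions), SmoM2 hemisphere replicate 1 and wild type hemisphere replicate 1 (hemisphere), SmoM2 vermis replicate 2 and wild type hemisphere replicate 1 (vermis), and SmoM2 vermis replicate 1 and wild type hemisphere replicate 1 (SmoM2 regions).

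The values have no detection call, so signal over background limits statements on dim genes: En1 in the hemisphere and Sowaha, Cbln4, Vip and Saa1 in wild type lie below or near the lower quartiles, and their folds are compressed there.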

Other observations

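The contrast of regions averaged over both genotypes was a test chosen only after the splits of the samples were seen, and the labelings within pairs after the p over all labelings. The size of the response was predicted before its test.

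Other gene groups changed by SmoM2 had members moving both ways and did not pass as lists in either region. Among glycolysis genes 5 rose and 6 fell of 18 in the hemisphere and 3 rose and 6 fell in the vermis (list adjusted p = 0.99 and 0.849), with Hk2, a hexokinase, up by 1.98 ± 0.10 (SE, n = 3 arrays per group) and 2.03, and Tpi1, triosephosphate isomerase, at -1.02 and -0.78. BMP and TGF-beta genes rose in 2 and fell in 6 of 28 cases in the hemisphere and rose in 3 and fell in 5 in the vermis (0.719 and 0.505), with the ligand genes Bmp5 at 1.81 and 2.01 and Bmp6 at -0.64 and -0.97. Regional patterning factors rose in 5 and fell in 1 of 33 cases in the hemisphere and rose in 5 and fell in 4 in the vermis (0.334 and 0.948), Tshz3 by 1.96 and 2.16 and Tlx3 by 0.97 and 1.14. The median of that list was -0.03 and the mean 0.12 with a test direction of higher in the hemisphere, and -0.09 and 0.02 with a direction of lower in the vermis. Among Eph and ephrin genes 2 rose and 4 fell of 21 in the hemisphere and 4 rose and 2 fell in the vermis (0.719 and 0.602; median -0.09 against a mean of 0.09 in the vermis), where Epha5 (2.45 and 1.87) and Epha8 (2.32 and 2.19) rose and Ephb1 fell by 0.84 and 1.03.

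Cell cycle inhibitors and p53 targets rose in 2 and fell in 3 of 19 cases in the hemisphere and rose in 3 and fell in 2 in the vermis (0.719 and 0.897), with Cdkn1c, an inhibitor of cyclin-dependent kinases, at 0.81 and 0.66 and Trp53inp1 at -0.65 and -0.62. Meninges and fibroblast genes rose in 3 and fell in 5 of 19 cases in the hemisphere and rose in 2 and fell in 5 in the vermis (0.719 and 0.141), with Serping1, a complement inhibitor, at -1.23 and -1.35 and Ptgds, a prostaglandin synthase, at -1.38 and -1.28. Of 14 Purkinje cell genes 2 rose and 2 fell in the hemisphere and 3 rose and 5 fell in the vermis. Over the list alone 2 rose and 4 fell in the hemisphere and 3 rose and 8 fell in the vermis. Foxp2, a forkhead factor, rose by 0.91 and 0.97, while the list did not pass (0.706 and 0.139). Of 22 interferon response genes 1 rose and 1 fell in the hemisphere and 2 fell in the vermis (0.719 and 0.948).

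Averaged over both genotypes, 85 genes differed between the regions by limma, 11 higher in the hemisphere and 74 higher in the vermis, and 98 passed with the replicate number as a block. Genes higher in the hemisphere included Celsr1, a planar polarity cadherin (0.56 ± 0.10 SE, adjusted p = 0.0191), and Moxd1 (0.54). Genes higher in the vermis included Fam107a (-1.29 as hemisphere minus vermis), Maob, a monoamine oxidase (-0.88), and Syt4, a synaptotagmin (-0.91). They were named after their values were seen.

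Whether the response to SmoM2 was larger in the hemisphere was tested on the 404 genes that differed at least 2-fold between genotypes over all arrays. Their mean change in the direction of the effect was 1.48 in the hemisphere and 1.53 in the vermis, a difference of -0.0481 (two-sided exact permutation p = 0.235 over 400 labelings). These labelings do not keep the pairing of the numbers. Exchanging regions only within numbered pairs gave an exact permutation p of 0.188 over 64 labelings, where the smallest possible is 0.0312. Neither a larger nor a smaller response is shown by these values.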
